A study of Mus musculus with 6 samples.

How the data were processed

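RNA was profiled by laser-capture sequencing in 6 pools of cells from the mouse striatum, 3 pools from mouse 1 (female) and 3 pools from mouse 2 (male). Per the labels, an AAV5 vector mix was injected into the striatum and cells were collected 12 weeks later. Each pool held about 33 cells, picked as neurons by their nuclear GFP. Lysis buffer was put on the captured cells and the lysate went straight into Smart-seq2 library preparation with Tn5 tagmentation, a full-length protocol that reads polyadenylated RNA and keeps no strand information. No molecular identifiers are described, so reads are not independent molecules.

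The deposited values are RPKM, read numbers scaled to transcript length and to the mapped reads of the library, calculated by the authors in 1 table with a row per gene and a column per pool. Per the submitters' processing notes, STAR 2.4.1, featureCounts 1.4.6 and Cufflinks 2.2.1 were used with the mm10 genome build; their roles, their order, the annotation and the treatment of reads that map to several places are not given in the sources used here. The table had 24582 rows: 24489 gene rows, eGFP, and 92 ERCC spike-in controls. 494 rows repeated a symbol, 185 joined several symbols and 27 symbols had been turned into dates, and such rows were kept apart and never named. Every one of the 6 pools had its own column. Gapdh stood at 2.94 to 24.3 RPKM and Ppia was listed at 0 in 5 of 6 pools, although cells in general use both genes heavily. Both have many near-identical copies in the genome, so values of genes with close copies are uncertain, as are those of overlapping or antisense genes.

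Depth was recovered from the RPKM values themselves. Among 5263 genes with a single transcript, 244 to 402 low values per pool were compared with whole multiples of 1 read. Of these low values 59.3% to 66.0% came within 0.1 of a whole number. The depth was itself fitted to values of these genes, so the shares are no independent check of it. The estimates were 3.63e+06, 4.34e+06 and 3.74e+06 reads for replicates 1, 2 and 3 of mouse 1, and 3.11e+06, 3.31e+06 and 3.84e+06 for those of mouse 2. They are approximate, since the authors' transcript lengths are not known. At these depths an RPKM of 1 in a transcript of 2 kb rests on 6.21 to 8.69 reads. RPKM are not counts, and no count model was fitted.

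The values were transformed to log2(RPKM + 1). This scale understates fold changes of weakly expressed genes, and a log2 difference of a gene listed at 0 in a mouse depends on the pseudocount and bounds nothing. The marker lists, the tests, the rule for naming genes and the alternatives were fixed before the data were examined, as 22 lists with 213 symbols. All 213 were found, 2 of them (Drd1 and Scn2a) under an older symbol. A list's level in a pool is the mean log2(RPKM + 1) of its members. 12 differences between lists were tested within pools by an exact two-sided sign-flip permutation test over the 6 pools with Benjamini-Hochberg adjustment over the 12; the smallest p this test can give is 0.03125. List medians were ranked among those of 10000 random lists of the same size drawn from all genes. Mouse 2 was compared with mouse 1 by limma 3.58.1 (R 4.3.3) with an intensity trend, over 13182 genes with a mean RPKM of at least 1, at a Benjamini-Hochberg adjusted p of 0.05. Lists were compared by limma's camera with a preset inter-gene correlation of 0.01, again with an estimated correlation, and by fry. Similarity of pools was the Spearman correlation across genes, with an exact permutation test of the mouse label. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Gene positions are those of GENCODE vM21 on GRCm38, the assembly that mm10 denotes.

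The unit of replication is the animal, and each mouse is 1 animal. Pools of a mouse repeat the capture and the library, so p-values over pools measure the spread between pools and are too small for statements on animals. Mouse and sex cannot be separated in this design, and no group without reprogramming was analysed here. The limma procedure was tested on simulated data made from the 13182 genes: of 50 genes changed at each size, 0% were recovered at a log2 change of 1, 2% at 2, 8% at 3 and 22% at 4, and 1 unchanged gene was called. Most changed genes were therefore missed in this simulation, which took the observed SDs as the true ones. The share found depends on how many genes change, so it does not give the share missed in these data.

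Genes named in the text were chosen by rule: in each list the 2 members with the highest and the 2 with the lowest mean RPKM, the member a list is named for and all 3 reprogramming factors; the 20 genes with the highest mean log2 value; for the comparison of mice, up to 15 genes per direction that passed the test, had non-overlapping pools and the largest log2 difference, and the sex chromosome genes; and the 10 most variable genes with a mean RPKM of at least 10. Exceptions are marked. Alternatives were a pseudocount of 0.1, rescaling to a common total per pool, quantile normalization, median centring, no filter or a mean RPKM of at least 5, limma without trend or with robust variances, the replicate number as a block, list medians, detected members only, means per mouse, Pearson correlation, detection at an RPKM of 0.1 or 5, and leaving out each pool in turn. A further 10 lists were added after the results of the fixed lists were seen, and their results are kept to the closing section.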

Results

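In a study of the conversion of NG2 glia, the progenitor glia of the adult brain, into neurons in the living striatum, cells were collected by laser capture and their RNA was sequenced. Conversion had been driven by AAV5 vectors for Ascl1, Lmx1a and Nurr1 (gene symbol Nr4a2), transcription factors used to turn other cells into neurons, the last 2 of them known from midbrain dopamine neurons. The 6 pools of about 33 cells each, picked as GFP-positive neurons per the labels, came from 2 animals at 12 weeks, 3 pools per mouse; no value here measures an origin from NG2 glia. The estimated depth was 3.63e+06, 4.34e+06 and 3.74e+06 reads in replicates 1, 2 and 3 of mouse 1 and 3.11e+06, 3.31e+06 and 3.84e+06 reads in those of mouse 2. Genes with an RPKM of at least 1 numbered 10578, 10844 and 10967 in replicates 1, 2 and 3 of mouse 1 and 10737, 6685 and 11655 in those of mouse 2, a mean of 10244 ± 1783 (SD, n = 6). Spike-in RNA made up 0.884% to 1.14% of summed RPKM in mouse 1 and 2.61%, 6.02% and 1.52% in mouse 2. There was 1 condition and no untreated group, so marker lists were compared with each other within each pool, and the 2 mice were compared with each other.

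The reporter and the delivered factors came first, since the pools had been picked by GFP. The eGFP transcript reached 123, 221 and 197 RPKM in the pools of mouse 1 and 18.3, 0.839 and 0.362 RPKM in those of mouse 2, a log2 difference of −5.59 (limma adjusted p = 0.0165). The reprogramming factor list moved with it: 2 of its 3 members were lower in mouse 2, and a log2 level of 7.10 ± 0.74 in mouse 1 (SD, n = 3) stood against 2.94 ± 2.31 in mouse 2 (SD, n = 3). Lmx1a (chromosome 1, 167689237 to 167848741, plus strand) measured 259 ± 95.9 RPKM in mouse 1 and 17.1 ± 20.1 in mouse 2 (SD, n = 3 each), a log2 difference of −4.66 ± 0.97 (SE; limma adjusted p = 0.0327). Nr4a2 (chromosome 2, 57106830 to 57124003, minus strand) was at 106, 251 and 234 RPKM in mouse 1 and at 11.1, 0 and 7.74 in mouse 2, a log2 difference of −5.29 ± 0.95 (SE; limma adjusted p = 0.0178). Ascl1 (chromosome 10, 87490819 to 87493660, minus strand) was at 24.5, 76.8 and 90.5 RPKM against 38.3, 0 and 22.2, which did not pass (log2 difference −2.55, limma adjusted p = 0.340). The list passed camera with the preset correlation (adjusted p = 0.00473) and not with an estimated one (adjusted p = 0.359). Pools of a mouse share that animal, so these p-values compare 2 animals and are too small for animals in general. The calls of eGFP, Lmx1a and Nr4a2 were lost with a pseudocount of 0.1 and each in 5 of the 6 fits that left out a pool (the exception was mouse 2 replicate 1 for eGFP and mouse 2 replicate 2 for the factors), with log2 differences of −5.85 to −4.88, −5.69 to −4.40 and −5.97 to −5.07 in those 5 and −6.80, −3.51 and −4.17 in the exceptions. The call of Lmx1a was also lost without a filter and by limma without trend. The list call was lost without mouse 2 replicate 3. The table does not separate transcripts of the delivered genes from those of the resident genes.

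**Figure D1:**
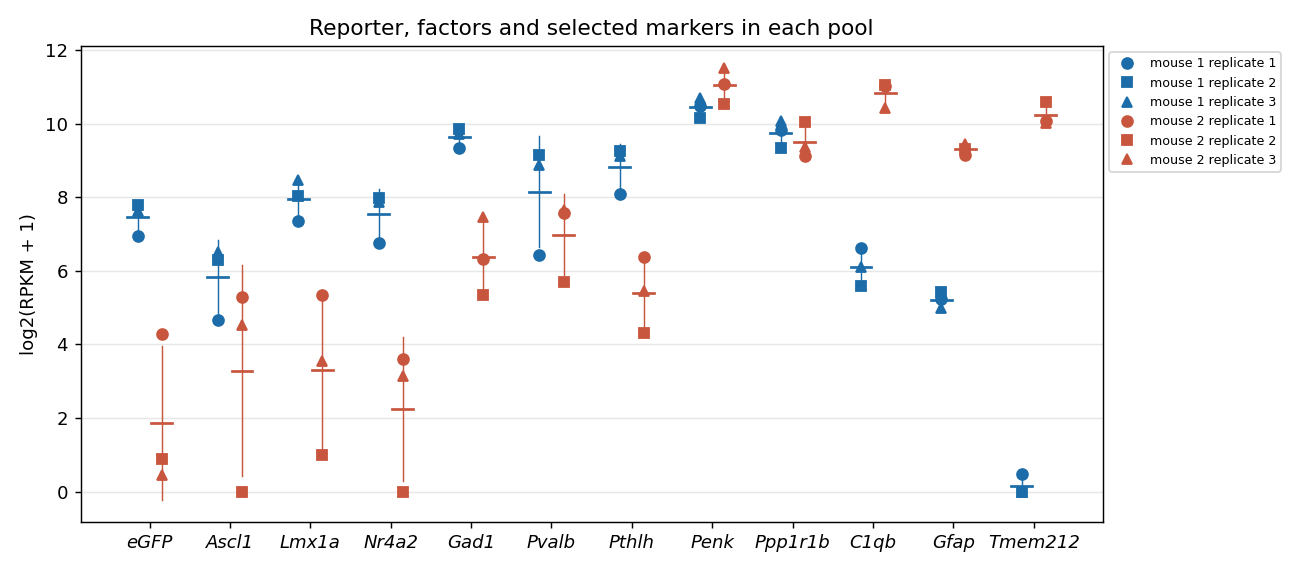
Level of the reporter, the factors and selected markers in each of the 6 pools, as log2(RPKM + 1) on the vertical axis; points are pools, horizontal bars the mean and vertical lines the SD of 3 pools per mouse. eGFP lies at 123 to 221 RPKM in mouse 1 and at 18.3 RPKM or less in mouse 2, and Tmem212 at 1034 RPKM or more in mouse 2 and at 0.385 RPKM or less in mouse 1.

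The first question was whether the captured cells carried neuronal rather than glial transcripts. Genes shared by most neurons were far above those of NG2 glia in every pool: the pan-neuronal list exceeded the NG2 list by 4.34 log2 units, 5.07 ± 0.34 in mouse 1 and 3.61 ± 0.65 in mouse 2 (SD, n = 3 each). Snap25 (chromosome 2, 136713453 to 136782428, plus strand), a component of the synaptic vesicle fusion machinery, reached 2202 ± 163 RPKM in mouse 1 and 622 ± 156 in mouse 2 (SD, n = 3 each). Gap43, a growth cone protein, reached 733 ± 286 and 416 ± 191 RPKM. Nefh, a neurofilament subunit, and Dlg4, a postsynaptic scaffold, were the weakest members, at 16.4 ± 3.70 and 4.25 ± 1.88 RPKM in mouse 1 and 2.23 ± 3.25 and 3.24 ± 5.19 in mouse 2. Among NG2 glia genes, Cspg4, which encodes NG2 itself, was at 1.92, 1.20 and 2.66 RPKM in mouse 1 and 0, 0 and 2.04 in mouse 2, Pdgfra was listed at 0 in 5 pools and at 2.05 in mouse 2 replicate 3, and Gpr17 was listed at 0 in all 6. The highest members, Ptprz1 and Olig1, had 6.75 ± 4.20 and 11.2 ± 17.8 RPKM in mouse 1 and 28.8 ± 7.45 and 13.9 ± 14.5 in mouse 2. The pan-neuronal list also exceeded the endothelial list by 3.79 (5.21 and 2.37 in mice 1 and 2) and the pericyte and smooth muscle list by 4.77 (5.29 and 4.25). These 3 differences were positive in 6 of 6 pools (exact sign-flip p = 0.03125, the smallest possible; adjusted p = 0.0417 over 12 contrasts). Pools of a mouse share that animal, so these p-values are too small. Over the 2 mouse means the smallest possible p is 0.5. Lists can also differ in how abundant their genes usually are, and no reference cells were analysed. The sign of a list difference, here and below, therefore does not by itself show which cells the pools held.

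Against astrocyte and microglia lists the animals parted, and against oligodendrocytes their pools overlapped. The pan-neuronal list lay above the astrocyte list by 2.81 ± 0.30 in mouse 1 and below it in mouse 2, at −0.88 ± 0.28 (SD, n = 3 each). Against microglia the difference was 2.85 ± 0.68 in mouse 1 and −2.50 ± 0.54 in mouse 2, and against oligodendrocytes 2.50 ± 1.25 and 0.33 ± 2.46. Over the 6 pools the means of 0.97, 0.17 and 1.42 did not pass the exact sign-flip permutation test (adjusted p = 0.307, 0.875 and 0.188, positive in 3, 3 and 5 of 6 pools), a test in which pools again share animals. Of the myelin genes, Mbp was at 177 ± 80.8 RPKM in mouse 1 (SD, n = 3) and at 3986, 229 and 537 in the pools of mouse 2, and Plp1 at 87.1 ± 63.5 and at 846, 0.269 and 265. Ermn and Ugt8a, the weakest oligodendrocyte genes, were each listed at 0 in 2 pools and did not exceed 43.3 RPKM. The level of the oligodendrocyte list was 4.12 ± 1.23 in mouse 1 and 4.95 ± 2.77 in mouse 2, that of the NG2 list 1.56 ± 0.32 and 1.68 ± 0.86.

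**Figure D2:**
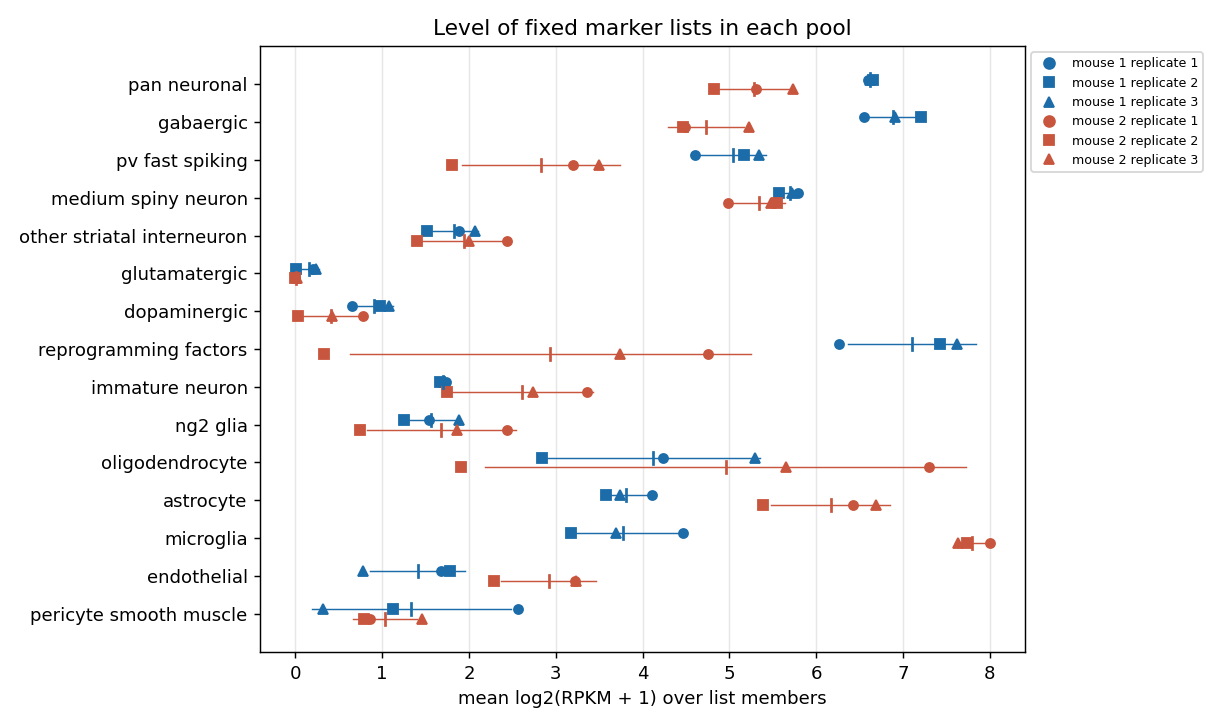
Level of 15 fixed marker lists in each of the 6 pools, as mean log2(RPKM + 1) over list members on the horizontal axis; symbols are pools, vertical ticks the mean and horizontal lines the SD of 3 pools per mouse. The microglia list lies at 3.78 ± 0.65 in mouse 1 and at 7.79 ± 0.19 in mouse 2, and the medium spiny neuron list at 5.70 ± 0.11 and 5.34 ± 0.31.

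The second question was which transmitter the neurons were equipped for. Of 5 GABAergic genes 4 had an RPKM of at least 1 in all 6 pools, and glutamatergic genes were close to absent from the values: the GABAergic list exceeded the glutamatergic list by 5.73 log2 units (6.74 ± 0.43 in mouse 1, 4.72 ± 0.42 in mouse 2, SD, n = 3 each) and the dopaminergic list by 5.15 (5.99 ± 0.21 and 4.32 ± 0.56). Gad1 (chromosome 2, 70553072 to 70602014, plus strand), which makes GABA from glutamate, measured 802 ± 141 RPKM in mouse 1 and 98.4 ± 70.3 in mouse 2. The GABA transporter Slc6a1 measured 217 ± 55.0 and 55.2 ± 17.4 RPKM, the GABA-degrading Abat 95.3 ± 26.5 and 38.4 ± 25.4, and the vesicular transporter Slc32a1 7.37, 13.5 and 4.86 against 2.76, 0 and 1.48 RPKM. Of 7 glutamatergic genes 5 were listed at 0 in all 6 pools, Neurod2 and Neurod6 among them. Slc17a7 was at 1.13 RPKM in mouse 1 replicate 1 and 0.0885 in mouse 2 replicate 3 and at 0 elsewhere, and Satb2 at 0.261, 0.0435 and 2.23 in mouse 1 and at 0 in mouse 2. Of 10 dopaminergic genes 6 were listed at 0 in all pools, Foxa2 and Lmx1b among them. Th, the rate-limiting enzyme of dopamine synthesis, was at 0, 29.0 and 36.5 RPKM in mouse 1 and at 0, 0 and 0.148 in mouse 2. The vesicular monoamine transporter Slc18a2 was at 12.8, 13.3 and 7.03 RPKM against 7.03, 0.0794 and 11.6. The GABAergic contrasts held in 6 of 6 pools (exact sign-flip adjusted p = 0.0417 each; pools share animals, so this p is too small). Depth allowed about 1 read in a transcript of 2 kb at an RPKM of 0.115 to 0.161, and a 0 does not exclude expression.

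The third question was the neuronal subtype. Genes of fast-spiking parvalbumin interneurons were above those of other striatal interneurons by 2.05 log2 units (3.21 ± 0.47 in mouse 1, 0.88 ± 0.56 in mouse 2, SD, n = 3 each) and above dopaminergic genes by 3.28 (4.13 ± 0.16 and 2.42 ± 0.65). They lay below the genes of medium spiny neurons, the main projection neurons of the striatum, by −1.58 (−0.66 ± 0.46 and −2.51 ± 1.08), and medium spiny genes exceeded other interneuron genes by 3.63 (3.87 ± 0.20 and 3.39 ± 0.80). Pvalb (chromosome 15, 78191114 to 78206400, minus strand), the calcium buffer that names the first list, was at 84.9, 566 and 472 RPKM in mouse 1 and 190, 51.2 and 198 in mouse 2. Pthlh, a peptide of the same interneurons, measured 476 ± 182 and 48.0 ± 31.9 RPKM. Erbb4 was at 3.63, 6.60 and 4.90 RPKM in mouse 1 and at 1.59, 0 and 0 in mouse 2, and Syt2 at 10.5, 0 and 1.11 and at 0 in mouse 2. Penk (chromosome 4, 4133531 to 4138819, minus strand), the enkephalin precursor of indirect-pathway medium spiny neurons, measured 1407 ± 269 and 2175 ± 707 RPKM, and Ppp1r1b, the dopamine signalling protein DARPP-32, 874 ± 212 and 756 ± 268. The weakest medium spiny genes were Isl1 at 40.1, 14.8 and 3.60 against 0, 11.5 and 0.206 RPKM, and Foxp2 at 13.1, 2.73 and 6.37 against 7.22, 0 and 10.7. Somatostatin (Sst) measured 384 ± 413 and 432 ± 273 RPKM, and Npy 0, 3.38 and 64.8 against 91.6, 67.1 and 13.4. The cholinergic genes Chat and Slc18a3 were listed at 0 in 5 of 6 pools each. All 4 subtype contrasts held their sign in 6 of 6 pools (exact sign-flip adjusted p = 0.0417 each, too small because pools share animals). The other interneuron list joins genes of several cell types, and 3 of its 11 members reached an RPKM of 1 in no pool, which lowers its mean. With only members detected in some pool the excess over it fell to 1.37 and did not pass (exact sign-flip adjusted p = 0.167). The excess was then 2.56 in mouse 1 and 0.18 in mouse 2, and positive in 4 of 6 pools. In mouse 2 the mean of Sst alone was above every value of Pvalb, so the lists do not rank single interneuron types.

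Across all lists, 84 of 213 symbols had an RPKM of at least 1 in all 6 pools and 18 were listed at 0 in all. As a description of these libraries, the list median lay at percentile 100 of 10000 random lists for pan-neuronal, medium spiny and microglia genes and at 99.97 for GABAergic and astrocyte genes. It lay at 99.96 for housekeeping, 99.93 for synaptic receptors, 99.72 for oligodendrocytes, 98.75 for immediate early and stress genes, 98.61 for interferon response, 98.16 for fast-spiking interneurons, 97.48 for the factors and 96.78 for ion channels. Endothelial (85.37), immature neuron (77.82), NG2 glia (70.11) and sex chromosome (56.43) lists lay within the range of most random lists. So did other interneuron (54.6), proliferation (48.71) and pericyte (47.79) lists. The glutamatergic and dopaminergic list medians were 0, the lowest value possible. Only random lists below a median were counted, not ties, so the percentile of these 2 lists was fixed at 0 and ranks them against nothing. The 20 genes with the highest mean log2 value over the pools included the cytoskeletal Tmsb4x and Actb and the calcium sensors Calm1 and Calm2. Also among them were the neuropeptide gene Penk and Cpe (its processing enzyme), the neuronal Snap25 and Pcp4, and Apoe, Cst3, Fth1 and B2m. The others were Sepw1, Tspan7, Cox4i1, Gnb1, Ubb, Aldoa, Gnas and Malat1. Calm2 or Tmsb4x was the highest gene in the pools of mouse 1, at 4017 to 6627 RPKM, and Apoe in every pool of mouse 2, at 18120 to 24599. The 20 highest genes of a pool took 9.01% ± 0.595 of summed RPKM in mouse 1 and 17.7% ± 1.06 in mouse 2 (SD, n = 3 each).

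The mice were then compared directly. Higher in mouse 2 were 8 of 12 microglia and 6 of 11 astrocyte genes, and lower were 2 of 5 GABAergic and 2 of 10 fast-spiking genes. With median centring 6 microglia, 3 astrocyte, 0 GABAergic and 0 fast-spiking genes passed, and without trend 8, 3, 0 and 1. Ctss (chromosome 3, 95526786 to 95556403, plus strand), a lysosomal protease of microglia, rose from 45.6 ± 11.8 RPKM in mouse 1 to 2648 ± 517 in mouse 2 (SD, n = 3 each; log2 difference 5.84 ± 0.28 SE, limma adjusted p = 2.23e-05). C1qb (chromosome 4, 136880129 to 136886187, minus strand), a complement subunit, rose from 70.4 ± 24.6 to 1850 ± 416 RPKM (4.73 ± 0.31, adjusted p = 0.000152), and Gfap (chromosome 11, 102887336 to 102900912, minus strand), the astrocyte filament protein, from 36.2 ± 5.59 to 630 ± 63.2 (4.09 ± 0.31, adjusted p = 0.000326). Apoe (chromosome 7, 19696109 to 19699188, minus strand), a lipid carrier made by astrocytes and microglia, rose from 696 ± 108 to 20556 ± 3526 RPKM (4.88 ± 0.14, adjusted p = 7.72e-07). Gad1 fell from 802 ± 141 to 98.4 ± 70.3 RPKM (−3.25 ± 0.48, adjusted p = 0.00754) and Snap25 from 2202 ± 163 to 622 ± 156 (−1.85 ± 0.20, adjusted p = 0.0014). The test called 488 of 13182 genes, 354 higher in mouse 2 and 134 higher in mouse 1; the median log2 difference of all 13182 genes was −0.29, and 0.02 without mouse 2 replicate 2. The 3 pools of a mouse share that animal, so the test compares these 2 animals, the p-values are too small for more than that, and animal and sex cannot be separated. With values centred on each pool's median the count was 260, split 244 and 16. Without mouse 1 replicate 1, 2 or 3 it was 118, 121 or 132. Without mouse 2 replicate 1, 2 or 3 it was 21, 888 or 108. The calls of Ctss, C1qb, Gfap and Apoe were kept in all 15 alternative fits. That of Gad1 was lost without mouse 2 replicate 1 (−3.23) and without any pool of mouse 1 (−3.40 to −3.15), and that of Snap25 without mouse 2 replicate 1 (−1.64) or mouse 1 replicate 1 (−1.80); both were lost with median centring.

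**Figure D3:**
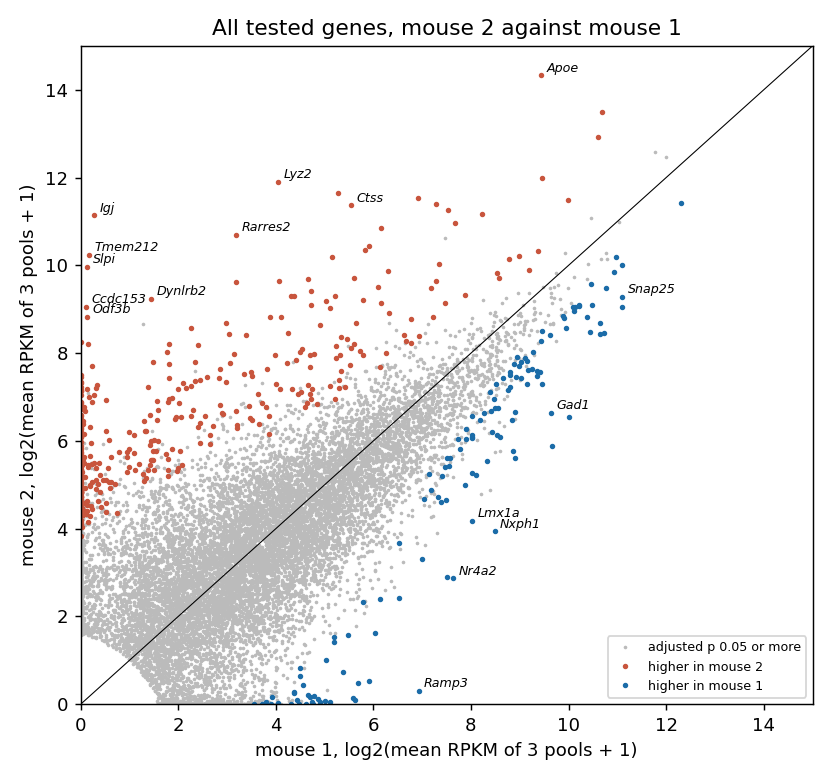
Each of the 13182 tested genes by its mean RPKM over 3 pools in mouse 1 (horizontal axis) and mouse 2 (vertical axis), both as log2(mean RPKM + 1); coloured points passed limma at an adjusted p of 0.05 and the line marks equal values. Of the coloured genes 354 lie above the line and 134 below it, with Igj, Tmem212 and Slpi near 0 in mouse 1.

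Genes with the largest rise in mouse 2 were nearly all at or near 0 in mouse 1. Igj, the joining chain of secreted antibodies, went from 0, 0.110 and 0.509 RPKM to 2129, 3044 and 1593 (log2 difference 10.84 ± 0.49 SE, limma adjusted p = 1.98e-05). Tmem212, a gene of ciliated cells, went from 0.385, 0 and 0 RPKM to 1071, 1527 and 1034 (10.06 ± 0.52, adjusted p = 3.17e-05). Ccdc153, Odf3b and Dynlrb2, genes of ciliated cells, rose by 8.94, 8.60 and 8.34. 1700012B09Rik rose by 8.02. Among secreted and immune genes, Slpi rose by 9.24, Rarres2 by 8.85, the lysozyme gene Lyz2 by 8.62 (15.5 ± 18.3 to 3813 ± 207 RPKM) and Saa3 by 7.48. The galectin gene Lgals3, the dynein light chain gene Tctex1d4, Mlf1, 1700009P17Rik and 1500015O10Rik were listed at 0 in every pool of mouse 1 and measured 179 ± 94.9, 159 ± 51.7, 140 ± 20.3, 304 ± 74.5 and 174 ± 93.6 RPKM in mouse 2 (SD, n = 3 each). Of these 15 genes the 10 with the largest rise were also the 10 most variable genes between pools. That variability was taken over the pools of both mice, so it largely restates the difference between them. Higher in mouse 1 were Ramp3 (64.7, 148 and 149 RPKM against 0, 0.267 and 0.460; log2 difference −6.53 ± 0.75 SE, adjusted p = 0.00197) and Nxph1, a synaptic ligand of neurexins (357 ± 32.4 against 14.4 ± 22.5 RPKM; −5.99 ± 1.10, adjusted p = 0.0194). Slc7a3, Fkbp1b, Tuba8, A530058N18Rik, Tmem126b and Il1rapl2 were lower in mouse 2 by between −5.48 and −5.04, as was Nr4a2. The calcium sensor Vsnl1 differed by −4.88 (805 ± 73.7 against 58.1 ± 53.6 RPKM, limma adjusted p = 0.0499), and Opn3, E030019B13Rik and Lmx1a by between −4.87 and −4.66. The call of Vsnl1 was lost in 10 of 15 alternative fits, with log2 differences of −5.88 to −3.25 over the 15. Dand5 and Cntfr measured 28.9 ± 7.37 and 25.7 ± 9.46 RPKM in mouse 1 and were listed at 0 in mouse 2. The pools of the mice did not overlap in 24.5% of the 13182 genes, where chance gives 10%; the balance was opposite to that of the calls, with 1869 genes higher in mouse 1 and 1356 higher in mouse 2. Adjusted p-values here compare 2 animals, since pools share an animal. Without mouse 2 replicate 1 or replicate 3 the calls of Slpi (8.59 and 8.78), Rarres2 (8.58 and 8.98) and Lyz2 (8.57 and 8.65) were lost. Those of Dynlrb2 (8.17), Saa3 (7.27), Lgals3, Mlf1, Tctex1d4 and 1500015O10Rik were lost without mouse 2 replicate 1. All 15 genes higher in mouse 1 lost their call without mouse 2 replicate 1 (−6.39 to −4.77, leaving aside Dand5 and Cntfr) and without mouse 1 replicate 2 (−6.34 to −4.63) or replicate 3 (−6.33 to −4.40), and all but Ramp3 without mouse 1 replicate 1 (−6.06 to −4.61). 10 of the 15 lost it without mouse 2 replicate 3: A530058N18Rik, Il1rapl2, Tmem126b, Nr4a2, Vsnl1, Opn3, E030019B13Rik, Lmx1a, Dand5 and Cntfr (−5.88 to −4.57, again without the last 2). Tmem126b lost it without mouse 2 replicate 2 too (−4.38). The calls of Igj and Tmem212 were kept in all 15 alternative fits.

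By list, camera with the preset correlation called 4 of the 21 fixed lists higher in mouse 2: microglia, astrocyte, endothelial and immature neuron genes. None of the 4 passed with an estimated correlation (adjusted p = 0.0906, 0.0906, 0.201 and 0.359). Of 12 microglia genes 8 rose and 4 did not pass (11 adjusted over the list alone), with a median log2 difference of 4.31. The weakest members, Cx3cr1 and Itgam, were at 16.6, 18.0 and 11.03 and at 17.4, 6.07 and 11.96 RPKM in mouse 2 and at 1.76 RPKM or less in mouse 1. Of 11 astrocyte genes 6 rose (8 adjusted over the list alone), median 2.27, with Aldoc at 438 ± 139 and 1133 ± 309 RPKM; Fgfr3 and Gjb6 did not pass. Of 6 endothelial genes 1 rose, also adjusted over the list alone, Pecam1, named after its value was seen. The list's median was 1.63, and Cldn5 was at 30.4 ± 18.4 and 85.3 ± 22.0 RPKM. Of 7 immature neuron genes 1 rose (1 adjusted over the list alone), Sox11, a transcription factor of new neurons, from 9.96 ± 4.63 to 109 ± 13.5 RPKM. The list's median was 1.56, and Dlx5 did not pass (51.0 ± 13.7 and 31.2 ± 26.6). Adjusted p-values of the 4 lists with the preset correlation were 4.01e-18, 1.25e-08, 0.00772 and 0.00884. Pools share animals, so these p-values are too small. The calls of Sox11 and Pecam1 were lost without any pool but mouse 2 replicate 2 (3.01 to 3.65 and 3.97 to 4.49), and that of Aldoc without any pool (1.18 to 1.63). Median centring ended those of Sox11 and Pecam1 too. Without mouse 2 replicate 1 limma called 3 microglia, 1 astrocyte, 0 endothelial and 0 immature neuron genes, against 11, 8, 2 and 1 at an unadjusted p under 0.05 in that fit. The spike-in share was higher in the pools of mouse 2 too, and the eGFP transcript lower.

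Lower in mouse 2, by camera with the preset correlation, were the pan-neuronal, GABAergic, fast-spiking, ion channel and synaptic receptor lists. None passed with an estimated correlation (adjusted p = 0.176, 0.176, 0.256, 0.359 and 0.140). Of 17 pan-neuronal genes 2 fell (3 adjusted over the list alone), with a median log2 difference of −1.26. Of 5 GABAergic genes 2 fell, Gad1 and Slc6a1 (4 adjusted over the list alone), with a median of −2.05. Of 10 fast-spiking genes 2 fell (4 adjusted over the list alone), with a median of −2.41. Pthlh was among them, at −3.43 ± 0.56 (SE, limma adjusted p = 0.0115). Pvalb did not pass (−1.18, adjusted p = 0.441). None of 13 ion channel genes (0 also adjusted over the list alone) and none of 11 synaptic receptor genes passed limma over all genes (5 fell adjusted over the list alone), with medians of −2.02 and −1.69. Scn1b and Kcnq2 were at 277 ± 206 and 19.95 ± 1.81 RPKM in mouse 1 and 64.2 ± 24.7 and 15.2 ± 14.96 in mouse 2. The glutamate receptor genes Gria1 and Gria2 were at 116 ± 15.96 and 98.9 ± 12.6 against 43.5 ± 10.001 and 41.4 ± 26.4. Grin2a was listed at 0 in all pools. Adjusted p-values of the 5 lists with the preset correlation were 5.08e-05, 0.000293, 0.000291, 0.000729 and 0.000729. With an estimated correlation camera called 0 of 21 lists in all, 5 of them at an unadjusted p under 0.05, and fry called 10 of 21; again pools share animals. Of the 10 lists called with the preset correlation fry called 8, not the factors (adjusted p = 0.0652) or immature neuron genes (0.0808), and it called housekeeping (0.00533) and sex chromosome genes (0.0159) instead. At an unadjusted p under 0.05 the 5 lists held 9, 4, 6, 7 and 7 genes, and limma without trend called 0, 0, 1, 0 and 1. The calls of Pthlh and Slc6a1 were lost without any pool but mouse 2 replicate 2 (−3.92 to −3.21 and −2.20 to −1.84). With median centring, and without mouse 2 replicate 1, limma called 0 genes of the 5 lists (6, 4, 5, 3 and 8 at an unadjusted p under 0.05 without that pool). Centring made the 5 medians −0.72, −1.51, −1.87, −1.49 and −1.15.

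The remaining lists were not called by camera, although some alternatives called 3 of them higher in mouse 2: oligodendrocyte without mouse 1 replicate 3, without mouse 2 replicate 2 and with the replicate block, proliferation without mouse 2 replicate 2 and with median centring, and sex chromosome with rescaling, quantile normalization and median centring. The block rests on a replicate number that pairs nothing. Of 16 medium spiny genes 0 passed (0 adjusted over the list alone; median −0.22, and 0.31 with median centring; 1 lower and −0.40 without mouse 2 replicate 2), which does not show that they were equal, and neither Penk (log2 difference 0.59, limma adjusted p = 0.243) nor Ppp1r1b (−0.24, adjusted p = 0.665) did. No gene passed among 3 dopaminergic (median −1.29), 6 other interneuron (0.70; 0.29 without mouse 2 replicate 1 and 1.23 with median centring), 10 NG2 glia (−0.48, with a mean of 0.09), 11 oligodendrocyte (0.53; 2 higher adjusted over the list alone), 5 pericyte (−0.09), 5 proliferation (1.57) and 7 immediate early genes (−1.57). At an unadjusted p under 0.05 limma gave 1, 1, 2, 3, 0, 0 and 2 genes in these 7 lists and 1 medium spiny gene, and limma without trend or with robust variances called 0. Apart from oligodendrocytes, none of the 7 held a gene that passed adjusted over the list alone, and the directions of 3 lists turn with the scaling. The oligodendrocyte median was −0.36 with a pseudocount of 0.1 and −0.93 without mouse 2 replicate 1. Leaving out mouse 2 replicate 2 gave medians of −0.21 for dopaminergic, 0.33 for NG2 glia, 2.78 for oligodendrocyte, 0.31 for pericyte and −0.67 for immediate early genes, and limma then called 1 NG2 glia, 1 oligodendrocyte and 1 proliferation gene. With median centring the NG2 glia median was 0.05 and the pericyte median 0.44. Vtn and Rgs5 of the pericyte list, Ly6c1 of the endothelial list and Cdk1 of the proliferation list were listed at 0 in 1, 1, 1 and 3 pools. Pcna measured 26.3 ± 6.85 and 28.5 ± 6.10 RPKM, Egr1 131 ± 59.1 and 53.9 ± 49.7, and Junb 103 ± 53.5 and 59.5 ± 16.4. In the interferon list 3 of 9 rose, all of them genes of class I antigen presentation, and 0 by limma without trend or with median centring (7 at an unadjusted p under 0.05 in the trended fit). B2m went from 698 ± 375 to 4095 ± 1137 RPKM (limma adjusted p = 0.00365) and H2-D1 from 163 ± 125 to 1050 ± 154 (adjusted p = 0.00857), and the other was H2-K1, named after its value was seen. H2-D1 and H2-K1 resemble other class I genes, so their values are uncertain. Adjusted over the list alone 3 rose and 3 fell, and the list's median was −1.41 (−0.03 without mouse 2 replicate 2). Of 6 housekeeping genes 1 fell (adjusted over the list alone 1 rose and 3 fell; median −0.46, and 0.07 with median centring), Tbp, named after its value was seen. Hprt measured 377 ± 50.7 and 208 ± 87.1 RPKM and Gapdh 19.7 ± 7.64 and 4.06 ± 1.72. Of 4 sex chromosome genes 1 rose (2 higher and 1 lower adjusted over the list alone; median 2.399). The Y-linked Eif2s3y was at 0, 0 and 0.151 RPKM in mouse 1 and 57.6, 34.4 and 54.8 in mouse 2 (log2 difference 5.54, limma adjusted p = 0.00624), and Ddx3y at 0.0594, 0 and 0 against 40.3, 2.15 and 9.93. Kdm5d and Uty were listed at 0 in mouse 1, and Xist was at 1.85, 2.26 and 9.57 RPKM in mouse 1, labelled female, and at 0.0757 RPKM or less in mouse 2, labelled male. The glutamatergic list had no gene to test. Without mouse 2 replicate 1 the calls of B2m (2.44), H2-D1 (2.82), H2-K1 (2.77), Tbp (−4.52) and Eif2s3y (5.41) were lost, as they were without mouse 2 replicate 3 (2.83, 3.03, 3.13, −4.40 and 5.44) and without mouse 1 replicate 1 (2.58, 2.60, 2.32, −4.69 and 5.51). Pools share animals, so these p-values too are for the 2 animals only.

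Pools of mouse 1 resembled each other more than those of mouse 2. Spearman correlations across 13182 genes, which are not independent replicates, were 0.812 to 0.848 within mouse 1, 0.513 to 0.682 within mouse 2 and 0.458 to 0.627 between mice. The mean within mice exceeded that between mice by 0.160 (exact permutation p = 0.1, one-sided for a higher mean within mice, the smallest that 10 splits of 6 pools allow). It was 0.106, 0.0925 and 0.0954 without mouse 1 replicate 1, 2 and 3 (exact permutation p = 0.2 each), and 0.213, 0.207 and 0.245 without those of mouse 2 (exact permutation p = 0.1 each).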

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

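The tests of explanations and the splits in this part were chosen after the results they bear on had been seen.

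Neuronal against astrocyte and microglia transcripts went opposite ways in the 2 animals: the pan-neuronal list minus the astrocyte list differed by −3.69 log2 units between mouse 2 and mouse 1, and minus the microglia list by −5.35, with every pool of mouse 1 positive and every pool of mouse 2 negative (exact permutation p = 0.1 for each, the smallest that 3 pools against 3 can give, with pools sharing an animal). A lower neuron share in mouse 2, with other cells in the proportions of mouse 1, would raise their markers alike where neurons lack them. The microglia list rose more than the astrocyte list by 1.66 (SD between pools 0.564, and 1.29 with SD 0.401 without mouse 2 replicate 2). This gap does not decide the question, because astrocyte genes differed more widely among themselves. Over the alternative fits Aldoc differed by 1.18 to 1.92 and Gfap by 3.97 to 4.62. Quantile normalization left a difference of 3.97 (SD 0.493) in the microglia list. That is no test of lower sequencing depth, since RPKM are already scaled to it. The estimated depths overlapped, at 3.63e+06 to 4.34e+06 reads in mouse 1 and 3.11e+06 to 3.84e+06 in mouse 2. Ependymal cells, which line the ventricle beside the striatum, are a candidate source of part of the rise: a second ependymal list of 15 genes, written before its members' values were seen but after the most variable genes were known, had a median log2 difference of 5.20. Its most abundant members Fam183b and Rsph1 reached 348 ± 156 and 291 ± 97.8 RPKM in mouse 2 (SD, n = 3), although cells were picked by nuclear GFP. A difference between the animals, their sex included, stays open and untested, and no capture data here tell whether other cells entered the pools.

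Of 26 measures tested, 2 had a pool that stood apart from the other 5, and in both it was mouse 2 replicate 2. Chance would give about 1.3 measures with any of the 6 pools apart, and fewer with 1 given pool. Mouse 2 replicate 2 had 6685 genes with an RPKM of at least 1 against 10578 to 11655, and 6.02% of its summed RPKM came from spike-in RNA against 0.884% to 2.61%. Fewer reads cannot be the whole account, since mouse 2 replicate 1 had fewer estimated reads and yet 4052 more genes. Less captured RNA stays open: the spike-in share was 5.26 times the median of the other 5 pools, but as 1 of the 2 measures that set this pool apart it is no separate test. No biological explanation was tested for this pool.

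No medium spiny gene of 16 passed limma between the mice (1 at an unadjusted p under 0.05, 0 without trend), which does not show equality, while eGFP, 2 of 3 factors and 2 of 10 fast-spiking genes were lower in mouse 2 (the last 2 not with median centring). Fewer neurons of every kind in mouse 2 would lower both subtypes alike. The medium spiny list changed less than the fast-spiking list by 1.85 (SD between pools 0.832, and 1.22 with SD 0.386 without mouse 2 replicate 2). This gap does not decide the question, because fast-spiking genes differed among themselves. Over the alternative fits Pthlh differed by −3.92 to −2.89, while Pvalb did not pass. RNA of resident medium spiny neurons in the pools of both mice stays open: their list changed by −0.36 (SD 0.232; −0.46 with SD 0.222 without mouse 2 replicate 2), but that change is part of the pattern itself and supports no explanation of it, and the capture was guided by nuclear GFP. Whether reprogrammed cells made these transcripts themselves cannot be read from pools, and a difference between the animals stays open and untested.

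The comparison of mice called 488 genes and, by camera with the preset correlation, 10 of 21 lists (0 with an estimated one, 5 at an unadjusted p under 0.05, and 10 by fry). Of the 10 splits of the 6 pools into 3 and 3, 1 gave as many genes, the real one, and the highest other split gave 0 by limma. For lists it was again 1 of 10, with 5 as the highest other count. The splits are too few for a share under 0.05. Every other split also puts pools of both mice on each side. The difference between the mice then adds to the spread within a side and lowers the count, so the low counts support nothing.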

How the results depend on the processing

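Of the 12 list contrasts, the 9 that passed kept the direction of their mean in every alternative. With means per mouse (4.34 for pan-neuronal minus NG2 glia, 3.79 minus endothelial, 4.77 minus pericyte, 5.73 for GABAergic minus glutamatergic, 5.15 minus dopaminergic, −1.58 for fast-spiking minus medium spiny, 2.05 minus other interneuron, 3.28 minus dopaminergic, 3.63 for medium spiny minus other interneuron) 2 mice cannot give an exact p under 0.5. Leaving out a pool leaves 5, for which the exact p cannot go under 0.0625; the same contrasts then ran from 4.22 to 4.52, 3.64 to 3.87, 4.52 to 5.08, 5.61 to 5.83, 5.03 to 5.31, −1.76 to −1.27, 1.90 to 2.17, 3.11 to 3.44 and 3.44 to 3.84. Fast-spiking minus other interneuron was 1.37 with detected members only (adjusted p = 0.167; 0.0417 in the other alternatives over 6 pools), since dropping undetected members raises the mean of the other interneuron list. The 3 contrasts that did not pass stayed so. Pan-neuronal minus microglia was −0.46 with list medians. Pan-neuronal minus oligodendrocyte was 0.77 without mouse 2 replicate 2 and 2.00 without mouse 2 replicate 1.

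The count of 488 genes was 293 without a filter (15788 genes tested), 260 with median centring, 643 with quantile normalization, 363 with a pseudocount of 0.1, and 21 to 888 when a pool was left out (21 without mouse 2 replicate 1, 888 without mouse 2 replicate 2). The median difference of all genes was −0.29, moving to −0.47 on rescaling, −0.53 with a pseudocount of 0.1 and 0.25 with median centring. Of 103 called genes among those listed or named, 11 were kept in all 15 alternatives, 65 with median centring, 14 without mouse 2 replicate 1 and 88 without mouse 2 replicate 2. Tmsb4x, which did not pass (0.48), turned to −0.95 and passed with quantile normalization. Camera called 10 of 21 lists with the preset correlation, 0 with an estimated one (5 at an unadjusted p under 0.05; fry 10), and 9 to 12 when a pool was left out. With the replicate block the counts were 368 genes, 338 of them kept, and 11 lists; deviations of same-numbered pools had correlations of −0.0047, −0.0021 and 0.0053, so the pools share only a number. Among the 21 fixed lists the block ended no call and added the oligodendrocyte list. Similarity was 0.127 to 0.214 under other filters, 0.163 by Pearson and 0.0925 to 0.245 without a pool; a pseudocount or scaling cannot change ranks. The genes detected per pool averaged 7953 with an RPKM of at least 5. Except where stated the cause was not tested. Depth limits weak genes most: an RPKM of 1 in a transcript of 2 kb rested on 6.21 to 8.69 reads. Of simulated log2 changes of 4 limma found 22%, a share that belongs to that simulation, in which depth was not varied.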

Other observations

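A further 10 gene lists were written after the fixed lists had been tested, and the tests in this part were chosen then. The lists on microglia, disease-associated microglia, reactive astrocytes, oxidative phosphorylation and synaptic vesicles were written before the values of their members were seen. The other 5 were written after the most variable genes were known, so their direction is not independent of those genes. No symbol is in 2 lists. As above, pools share an animal, so p-values are too small and compare these 2 animals only.

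Of the added lists 6 were called higher in mouse 2 by camera with either correlation. Of 16 further microglia genes 10 rose (15 adjusted over the list alone), with a median log2 difference of 4.29; Cyba, an oxidase subunit, measured 24.2 ± 17.1 RPKM in mouse 1 and 826 ± 293 in mouse 2 (SD, n = 3 each), and Fcer1g, an immune receptor chain, 15.8 ± 13.6 and 797 ± 156. Of 15 ependymal genes 10 rose (14 adjusted over the list alone), median 5.20, and 0 of the 15 had an RPKM of at least 1 in all 6 pools. Of 11 disease-associated microglia genes 3 rose (5 adjusted over the list alone), median 2.89, with Cd9 at 33.5 ± 27.6 and 518 ± 67.6 RPKM and Cd63 at 43.1 ± 14.2 and 321 ± 80.9. Of 8 reactive astrocyte genes 3 rose (5 adjusted over the list alone), median 3.27, with the filament gene Vim at 6.24 ± 5.29 and 197 ± 60.2 RPKM. Of 6 macrophage genes 2 rose (3 adjusted over the list alone), median 3.49, among them Lgals3 at 0 in all 3 pools of mouse 1 and 131, 288 and 118 RPKM in mouse 2. Of 6 T-cell genes 1 rose (1 adjusted over the list alone), median 2.64, the chemokine gene Ccl5 at 19.2 ± 14.4 and 144 ± 59.7 RPKM, whose call was lost in 11 of 15 alternatives, among them the fits without any 1 of the 6 pools (log2 difference 2.42 to 3.62). With an estimated correlation these 6 lists passed too (adjusted p = 0.00745, 0.00745, 0.0448, 0.0324, 0.0448 and 0.0448). Without mouse 2 replicate 1 limma called 0 genes in each of the 6 lists, against 15, 13, 5, 4, 2 and 3 at an unadjusted p under 0.05 in that fit, while camera still called all 6 lists.

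Of 6 B and plasma cell genes 1 rose (1 adjusted over the list alone), median 2.39: Mzb1, at 0, 0 and 10.3 RPKM in mouse 1 and 292, 45.7 and 101 in mouse 2, a call lost in 7 of 15 alternatives, among them the fits without mouse 1 replicate 1 or 2 (log2 difference 5.05 each) or mouse 2 replicate 1 or 3 (4.94 and 5.70). Of 3 choroid plexus genes 0 passed limma (2 higher adjusted over the list alone, 2 at an unadjusted p under 0.05, 1 called by limma without trend), median 2.51, with Clic6 at 3.30 ± 1.43 and 25.6 ± 15.2 RPKM. Of 16 oxidative phosphorylation genes 3 fell (12 adjusted over the list alone), median −1.08, with Ndufa4 at 1193 ± 208 and 549 ± 163 RPKM and Atp5b at 1123 ± 227 and 526.1 ± 135. Of 12 synaptic vesicle genes 4 fell (8 adjusted over the list alone), median −2.00, with Rab3a at 1606 ± 239 and 347 ± 131 RPKM and Vamp2 at 684 ± 197 and 190 ± 129. These 4 lists passed camera with the preset correlation and not with an estimated one (adjusted p = 0.135, 0.122, 0.0636 and 0.0971). The choroid plexus list also failed with the replicate block (0.0734), quantile normalization (0.0513) and median centring (0.0632), and without mouse 1 replicate 2 (0.0597) or 3 (0.0622). With limma without trend, and with median centring, 0 oxidative phosphorylation and 0 synaptic vesicle genes passed (12 and 8 at an unadjusted p under 0.05 in the trended fit), and with centring the medians were −0.54 and −1.46. Fry called 9 of the 10 lists, all but that of B and plasma cells (adjusted p = 0.0530). Without mouse 2 replicate 1 limma called 0 genes in each of the 4, against 1, 2, 11 and 7 at an unadjusted p under 0.05 in that fit, and camera still called all but the choroid plexus list (adjusted p = 0.0568).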
